A study of Mus musculus with 28 samples.

How the data were processed

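The data were 28 mouse RNA libraries prepared with QuantSeq, a method that sequences tags from the 3′ ends of polyadenylated mRNAs, from cortex and heart. Per the labels, the libraries were sequenced on an Illumina HiSeq and reads were aligned with STAR to the mouse genome build GRCm38. The STAR version, the counting tool and the gene annotation are not given in the sources used here. The deposited files hold 1 raw read count per Ensembl gene and library, as made by the authors, and these counts were the only values used. All 28 files listed 55416 gene IDs, of which 52083 matched a gene symbol and 3333 did not. Of the unmatched IDs, 2147 began with ENSMUSG00002, a range that the annotation used here for names and positions, GENCODE M21, does not hold. Total counts per library ranged from 2997738 to 8779631, so 1 count equalled 0.114 to 0.334 CPM (counts scaled to a common library total). Whether tags of 1 molecule were collapsed is not given in the sources used here.

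Libraries were grouped by age, tissue and genotype as the labels give them, and the extraction kit was taken from the first passage of each library's protocol text. The 8 groups held 3 control and 3 Sepsecs Y334C libraries for each tissue at postnatal day 1 (P1), and 3 control and 5 Sepsecs Y334C, Gpx4 U/C libraries for each tissue at postnatal day 75 (P75). Per the series' design text, replicates were mice. Each mutant group was compared with the control group of its age and tissue, which gave 4 comparisons. In addition, 4 interaction terms were tested: heart against cortex at P1 and at P75, and P75 against P1 in cortex and in heart. The P75 mutants differ from the P1 mutants in age, in the Gpx4 allele and mostly in sex, and in heart also in the extraction kit, so the age terms cannot part these.

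Genes were kept with the filterByExpr function of edgeR 4.0.16 (R 4.3.3), normalised by trimmed mean of M values (TMM), and tested with the edgeR quasi-likelihood F test. P values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The prior count for log2 CPM was 2. Standard errors (SE) of log2 fold changes were taken as the size of the fold change divided by the square root of F. CPM of genes in the comparisons carry the TMM factors, with standard deviations (SD) over libraries, while figures, Cst7 and library checks use CPM of the library total. Every P1 comparison had 4 residual degrees of freedom.

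Before the data were examined, 51 gene lists were fixed, with at least 5 tested genes required for a test. They covered selenoproteins, the selenoprotein mRNAs known to follow selenium supply, stress and metabolic pathways, and marker genes of cell types and of neighbouring tissues. Each list was tested with camera (limma 3.58.1, preset correlation 0.01), which asks whether the list ranks apart from the other genes, and adjusted over the lists of a comparison. The camera test with an estimated correlation and the self-contained fry test were run as alternatives. List medians, means and numbers of higher and lower genes are those of the log2 CPM differences that camera tests, and can differ from the edgeR fold changes of single genes. Genes of a list were also counted adjusted over the list alone, from the edgeR p values.

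The naming rule for genes was also fixed then. Sepsecs and Gpx4 came first, followed by the selenoproteins as a group. Then came the 8 genes with the smallest p in each direction among those past the threshold, or the 3 smallest where none passed. The last part was up to 4 genes with the smallest p from each list past the threshold. Not every gene that the rule gives is printed. Genes known only by a clone or model name were not named, and sex-linked genes served only as a library check.

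Alternatives were RLE and upper-quartile normalization, haemoglobin and mitochondrial genes left out, no count filter, a mean count of at least 10, DESeq2 1.42.0, limma-voom with sample quality weights, the replicate number as a block, Xist level as a covariate, each library left out in turn, all 4 groups of a tissue in 1 fit, the extraction kit as a factor or RNeasy libraries alone, an adjusted p under 0.10, and a fold of at least 1.5. Chosen after the data were seen were a robust dispersion, a term for the P75 libraries numbered 2 or their removal, a term for the P75 libraries with Ccdc36 above 100 CPM or the removal of P75 heart control 1 with the number-2 libraries, camera on the interactions, the Xist, kit-subset and number-2 settings for the lists, and a test combined over the 4 comparisons.

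Whether libraries with the same number pair was checked from the counts, since the labels do not say so. Residuals from each group mean were correlated between same-number control and mutant libraries over all genes. Only in the P75 cortex did all same-number libraries correlate above 0.1, with r of 0.422 to 0.694. There 3 of 3 libraries correlated best with the library of their own number. For numbers 1 and 3 another number came close (0.422 against 0.329, and 0.504 against 0.428). Number 2 stood apart, at 0.694 against −0.533. The counts thus show a pattern shared by the number-2 libraries, and whether the other numbers pair is open. The smallest r was 0.048 in the P1 cortex, −0.164 in the P1 heart and −0.207 in the P75 heart. Blocked values are therefore given beside many of the P75 cortex results, with an unpaired test as the main one. In the blocked fit mutants 4 and 5 have no control of their number. The blocked difference thus rests on mutants 1 to 3, with fewer residual degrees of freedom than the unpaired fit. The block is set beside this comparison because of a pattern in these same counts, so its p values are not independent of that choice.

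The edgeR test was tested on counts simulated with the real library sizes and each gene's mean over all libraries of a comparison. In these counts 100 genes were changed 2-fold and 100 genes 4-fold. The test recovered 41% and 84% of them in the P1 cortex, 6% and 71% in the P1 heart, 24% and 79% in the P75 cortex, and 0% and 49% in the P75 heart. False calls numbered 5, 5, 9 and 2, and those of DESeq2 19, 10, 32 and 17. Genes were drawn independently of each other, without patterns shared by sets of libraries. The number of false calls in the real counts can therefore differ. For the interactions, recovery at 4-fold was 36% (P1 tissues), 30% (P75 tissues), 54% (cortex ages) and 5% (heart ages). There each gene started from the same mean in both tissues or at both ages, unlike in the real counts. All libraries were used and none was left out of the main tests. Reads were not realigned. The Y334C codon and the Gpx4 codon lie outside what gene counts show, so the genotypes were not checked.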

Results

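Gene expression was measured by 3′-end RNA sequencing in the cortex and heart of newborn and adult mice. The newborns (P1) carried Y334C, a human missense mutation, in Sepsecs, the enzyme that completes selenocysteine on its tRNA. The adults (P75) carried the same mutation and were labelled Gpx4 U/C, where U stands for selenocysteine and C for cysteine in that lipid peroxidase. The form with cysteine needs no selenium. The label names both forms, so a copy with selenocysteine may remain. Each P1 group had 3 libraries, and each P75 tissue had 3 control and 5 mutant libraries. The labels call the P75 controls Gpx4 wild type and do not give their Sepsecs genotype. Per the series title, Y334C mutants die around birth, so adult controls with wild-type Gpx4 are unlikely to share that genotype. Both alleles then differ together at P75, and a P75 difference cannot be assigned to either. Total counts were 5915059 to 7137720 in P1 cortex controls and 5062069 to 6912875 in mutants, and 5779075 to 7043838 in P1 heart controls and 4836866 to 7239310 in mutants. At P75 they were 2997738 to 6593897 in cortex controls and 3558689 to 6134241 in mutants, and 4737953 to 7305996 in heart controls and 5030080 to 8779631 in mutants.

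The genes that carry the alleles did not differ past the threshold in any comparison. Sepsecs (ENSMUSG00000029173; chromosome 5, 52640087 to 52669708 of GRCm38) had log2 fold changes of 0.46 ± 0.22 (SE) in the P1 cortex, 0.08 ± 0.29 in the P1 heart, 0.25 ± 0.35 in the P75 cortex and −0.20 ± 0.42 in the P75 heart. Gpx4 (ENSMUSG00000075706; chromosome 10, 80047166 to 80056439) had −0.10 ± 0.23, −0.09 ± 0.28, 0.67 ± 0.43 and −0.07 ± 0.44. The edgeR adjusted p was at least 0.904 in all 8 tests. The heart values changed sign under other settings, and that of Gpx4 at P75 moved to 0.71 without control 1 and 0.63 by limma-voom, with 14.5 ± 5.65 CPM of the library total in controls and 17.8 ± 6.17 in mutants, so its direction is open. Gpx4 counts were low, at 8.51 to 17.8 mean CPM in the 8 groups, and their split from tags of the pseudogene Gpx4-ps2 is uncertain.

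The P1 cortex comparison asked what the Sepsecs mutation alone does to brain mRNAs at birth. Among the genes with the smallest p were selenoprotein mRNAs, which encode proteins that contain selenocysteine. Selenow (ENSMUSG00000041571; chromosome 7, 15917208 to 15922402), a small redox protein of brain and muscle, averaged 148 ± 16.5 CPM (SD, n = 3) in controls and 73.9 ± 14.2 (n = 3) in mutants, a log2 fold change of −0.998 ± 0.172 (SE). Gpx1, the main cytosolic glutathione peroxidase, averaged 324 ± 36.4 and 168 ± 33.4 (−0.95 ± 0.17), and Selenoh, a nuclear redox protein, 68.8 ± 8.64 and 41.0 ± 2.89 (−0.75 ± 0.15). Each was below all 3 controls in 3 of 3 mutants, and chance gives such a separation, in either direction, in 10% of genes. Genes picked by a small p tend to separate, so the separation adds no support. On the other side stood Gabra2, a GABA receptor subunit, at 21.6 ± 6.87 and 72.9 ± 19.1 CPM (1.76 ± 0.28), Tet1, which oxidises methylcytosine (0.62 ± 0.16), and Cfap36 (0.56 ± 0.15), each above all controls in 3 of 3 mutants. These 6 genes had the smallest p in their direction and none passed over all genes. The edgeR test called 0 of 13694 genes, 287 had an unadjusted p under 0.05, limma-voom called 0, and DESeq2 called 3: Gabra2 (adjusted p = 9.18e-06, range over the alternatives 7.96e-14 to 1.0), Selenow (0.00292, range 5.47e-05 to 1.0) and Gpx1 (0.00413, range 6.77e-05 to 1.0). Leaving out control 1 gave 5 calls and leaving out mutant 3 gave 1.

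Of 24 selenoprotein genes, 21 were tested in the P1 cortex, and 11 were higher and 10 lower in mutants. Over all genes 0 passed with edgeR and 2 with DESeq2. With 7 at an unadjusted p under 0.05, the same number passed when adjusted over the list alone: Selenow, Gpx1, Selenoh and the thioredoxin reductase Txnrd1 (−0.55 ± 0.17) were lower, and Sephs2, which makes the selenium donor (0.59 ± 0.18), Selenot (0.51 ± 0.17) and Dio3 (1.70 ± 0.58) were higher. This count was 3 without control 1, without mutant 1 or without mutant 3, and 4 without control 2. The median of the list was 0.03, the mean −0.01 and the camera test pointed down (adjusted p = 0.603). The 5 mRNAs known to follow selenium supply (Gpx1, Gpx3, Selenow, Selenoh and Msrb1) were 0 higher and 5 lower, with a median of −0.74 and 3 of 3 mutants below all controls. Camera called this list (adjusted p = 1.63e-05), with adjusted p = 0.295 with an estimated correlation, and 3 of its genes passed when adjusted over the list alone against 0 over all genes. The call held without any 1 of the 6 libraries.

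Camera called 5 further lists of 45 in the P1 cortex, each with adjusted p = 0.936 with an estimated correlation, and 0 of their genes passed over all genes or adjusted over the list alone by edgeR, with 9 at an unadjusted p under 0.05. Astrocyte markers, genes of the glia that arise around birth, had a median of 0.39 with 18 of 19 higher (adjusted p = 6.30e-04, 2 of 3 mutants above all controls), among them Fgfr3 (0.67 ± 0.24) and Agt (2.21 ± 0.89). Endothelial genes, 16 of 18 lower, had a median of −0.32 (2.61e-04, 2 of 3 mutants below all controls), with Kdr (−0.57 ± 0.19), Tie1 (−1.09 ± 0.43) and Emcn (−1.04 ± 0.44). Extracellular matrix genes, 28 of 35 lower, had −0.34 (5.02e-05, 2 of 3 mutants), with Mmp2 (−0.96 ± 0.34), Postn (−0.71 ± 0.33) and Col1a1 (−0.61 ± 0.29). Ribosomal protein genes, 60 of 72 lower, had −0.13 (6.30e-04, 2 of 3 mutants below the control mean), with Rpl13a (−0.68 ± 0.22) and Rps28 (−0.39 ± 0.16), where the split from pseudogenes is uncertain. Cell-cycle genes, 29 of 38 lower, had −0.22 (0.00492, 2 of 3 mutants below the control mean), with Tyms (−0.76 ± 0.37) and Mcm4 (−0.46 ± 0.23). All 5 calls depended on single libraries. Matrix and endothelial genes lost the call without control 1 (medians −0.17 and −0.15), ribosomal genes without control 1, control 2 or mutant 3 (−0.09, −0.03 and −0.04), and cell-cycle genes without control 2, control 3 or mutant 1 (−0.07, −0.16 and −0.03), and with Xist level as a covariate their median was 0.11. Astrocyte genes lost it without control 1, control 2, mutant 1 or mutant 3 (0.23, 0.25, 0.27 and 0.16).

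**Figure D1:**
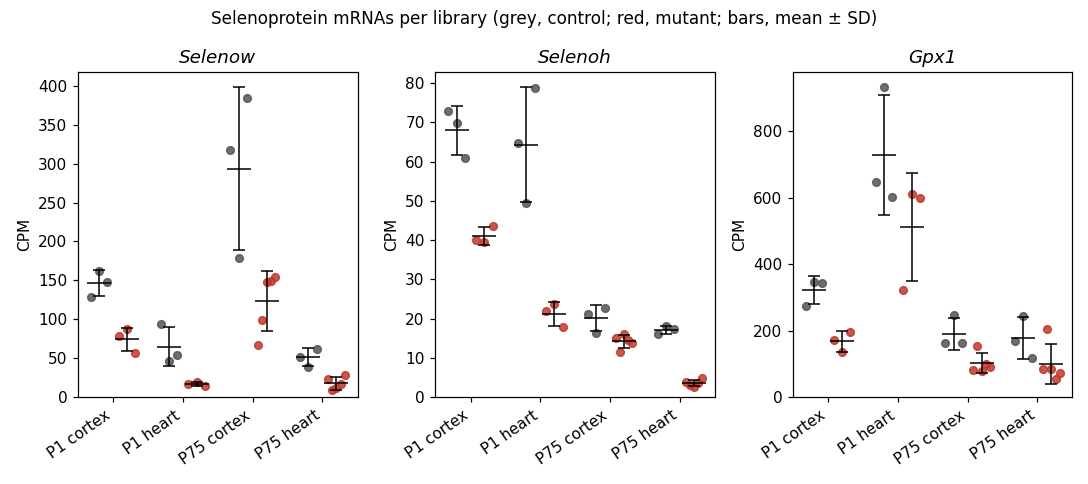
CPM of the library total of Selenow, Selenoh and Gpx1 for each library of the 4 comparisons (grey, control; red, mutant; bars, mean ± SD). Selenow and Selenoh lie below all controls in every mutant of the 4 comparisons, while Gpx1 overlaps the controls in P1 heart mutant 2 (610.5 CPM) and P75 heart mutant 2 (205.2 CPM).

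The P1 heart comparison asked about the same mutation in heart, since per the series title the mutants die around birth of cardiac and respiratory failure. Selenow averaged 64.0 ± 19.8 CPM in controls and 17.1 ± 2.37 in mutants (−1.91 ± 0.29), and Selenoh 64.4 ± 14.7 and 21.3 ± 2.56 (−1.60 ± 0.26). Asns, which makes asparagine and is a target of the amino-acid stress factor ATF4, averaged 4.94 ± 3.00 and 22.0 ± 7.07 (2.16 ± 0.45). Igfbpl1, a binding protein of growth factors, averaged 25.3 ± 4.49 and 7.89 ± 2.10 (−1.67 ± 0.30). All 4 separated the groups in 3 of 3 mutants. Gpx3 (−0.97 ± 0.41) and Gpx1 (−0.51 ± 0.30) were lower than the control mean in 3 of 3. The edgeR test called 0 of 12876 genes, with 326 at an unadjusted p under 0.05, and limma-voom called 0. DESeq2 called 10, 2 higher and 8 lower, among them Selenow (adjusted p = 1.57e-05, range over the alternatives 2.24e-06 to 1.00), Selenoh (2.02e-04, range 2.02e-04 to 1.00), Igfbpl1 (0.00373, range 0.00113 to 1.0) and Asns (0.00428, range 2.59e-06 to 1.0). Leaving out control 3 gave 14 calls, control 2 gave 3 and mutant 2 gave 1.

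Genes of the integrated stress response, the programme that ATF4 drives when amino acids run short or translation stalls, were 29 higher and 6 lower of 35 in the P1 heart. Their median was 0.39, with 3 of 3 mutants above all controls. Chac1, which degrades glutathione, had 3.07 ± 0.69 at low level (0.291 to 2.71 mean CPM), Phgdh, the entry to serine synthesis, 2.43 ± 0.57, and the mitochondrial folate enzyme Aldh1l2 1.43 ± 0.36. Camera called the list (adjusted p = 5.57e-08), with adjusted p = 0.0987 with an estimated correlation, and 7 genes passed adjusted over the list alone against 0 over all genes. Cholesterol synthesis genes were 4 higher and 18 lower of 22, with a median of −0.62 and 3 of 3 mutants below all controls (adjusted p = 2.24e-07, and adjusted p = 0.231 with an estimated correlation). Adjusted over the list alone 3 genes passed against 0 over all genes, among them Cyp51 (−0.89 ± 0.24) and Msmo1 (−0.98 ± 0.26), and Sqle (−1.18 ± 0.38) did not. Targets of NRF2, the factor that induces glutathione and quinone-reducing enzymes, were 21 higher and 5 lower of 26, with a median of 0.36 and 3 of 3 mutants above all controls (1.91e-05, and adjusted p = 0.231 with an estimated correlation). They included Nqo1 (0.87 ± 0.24), Gsta4 (0.79 ± 0.23), Me1 (0.96 ± 0.31) and Gstm1 (0.82 ± 0.32), of 6 with an unadjusted p under 0.05 by edgeR, and 0 passed over all genes or adjusted over the list alone. The selenium-sensitive list was 1 higher and 4 lower, with a median of −1.08 (−0.97 by the edgeR fold changes) and 3 of 3 mutants below all controls (7.64e-06, and adjusted p = 0.231 with an estimated correlation). Selenow and Selenoh passed adjusted over the list alone. These 4 calls held without any 1 of the 6 libraries. With Xist level as a covariate the medians were 0.12 for the stress response, −0.25 for cholesterol synthesis, 0.20 for NRF2 targets and −1.30 for the selenium-sensitive mRNAs, and all 4 passed.

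Camera called 11 more lists of 46 in the P1 heart, with adjusted p of 0.231 to 0.796 with an estimated correlation. Over all genes 0 of their members passed. All 20 selenoproteins tested had a median of −0.27 with 12 lower, or 13 by the edgeR fold changes (adjusted p = 0.00620, and adjusted p = 0.231 with an estimated correlation). Adjusted over the list alone 2 of them passed, and 0 did in the other 10 lists. Erythroid genes had a median of 0.79 with 16 of 19 higher (2.85e-05), such as Hba-a1 (6594 ± 4633 and 12630 ± 3865 CPM), where the split from a near-identical paralog is uncertain. Higher medians were also found for platelet (0.55, Ppbp 1.23 ± 0.59), neutrophil (0.67, S100a9 0.46 ± 0.24), macrophage (0.24, Itgam 1.42 ± 0.60) and glucocorticoid-responsive genes (0.49, Sult1a1 1.36 ± 0.59). Lower medians were found for immediate early (−0.48, Nr4a3 −1.87 ± 0.60), matrix (−0.22, Col8a1 −1.39 ± 0.55), unfolded protein response (−0.34, Hspa5 −0.51 ± 0.25), cell-cycle (−0.22, Mcm2 −1.29 ± 0.49 and Mcm3 −1.19 ± 0.47) and excitatory-neuron genes (−0.25, Cux2 −0.86 ± 0.41). Each of the 11 calls was lost when some single libraries were left out. Without control 1 the medians were 0.41 for erythroid, 0.40 for platelet, 0.58 for neutrophil, −0.07 for glucocorticoid-responsive, −0.23 for unfolded protein response and −0.28 for excitatory-neuron genes. Without control 2 they were −0.18 for selenoproteins, −0.24 for immediate early, −0.08 for matrix, −0.14 for excitatory-neuron and 0.34 for macrophage genes. Without control 3 they were −0.22 for unfolded protein response, 0.15 for cell-cycle, 0.42 for glucocorticoid-responsive, −0.14 for excitatory-neuron and 0.13 for macrophage genes. Without mutant 1 they were −0.19 for selenoproteins and −0.50 for excitatory-neuron genes, and without mutant 3 −0.12 for matrix and 0.40 for glucocorticoid-responsive genes. Without mutant 2 they were 0.18 for cell-cycle, 0.17 for glucocorticoid-responsive, −0.14 for excitatory-neuron, 0.04 for macrophage and 0.17 for neutrophil genes. With Xist level as a covariate erythroid and glucocorticoid-responsive genes were called in the other direction (−0.23 and −0.29), and the calls of unfolded protein response (−0.02), cell-cycle (−0.04), excitatory-neuron (−0.22), platelet (0.03) and neutrophil genes (0.25) were lost.

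The P1 heart libraries differed in extraction. Per the labels, controls 1 and 2 were extracted with TRIzol, and control 3 and the 3 mutants with the RNeasy Plus Micro kit, though a second passage of the same labels names TRIzol for every library. Scgb3a2, an airway gene, was at 2775 and 804.6 CPM in the TRIzol controls and at most 6.62 in the others, and Col2a1, a cartilage gene, at 64.2 and 113.0 against at most 2.97. The kit and neighbouring tissue in these 2 controls therefore cannot be told apart, and both limit the P1 heart results. Sftpc, a lung gene, was at 293.4 CPM in mutant 2. Among RNeasy libraries alone (1 control against 3 mutants, with the single control assumed to vary like the mutants), list medians were 0.64 for the stress response, 0.86 for NRF2 targets, −0.70 for cholesterol synthesis and −0.47 for the selenium-sensitive mRNAs, and all 4 passed camera. A single control cannot show that they stand apart from the kit. The calls of all selenoproteins (−0.39), immediate early (−0.44), matrix (−0.09) and excitatory-neuron genes (−0.27) were lost. All 6 P1 mutant libraries had 109 to 515 CPM of Xist and at most 0.503 of the Y-linked Ddx3y, while 2 of 3 controls in each tissue had 27.7 to 88.4 CPM of Ddx3y, so the comparison with mutants is partly one between sexes.

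The P75 cortex comparison asked which brain mRNAs differ when the rescued mutants reach adulthood. Gfap, the intermediate filament of reactive astrocytes, averaged 28.0 ± 8.37 CPM in 3 controls and 244 ± 113 in 5 mutants (3.11 ± 0.48). C4b, a complement component, averaged 3.65 ± 0.556 and 25.5 ± 9.57 (2.81 ± 0.41), and Etnppl, a lipid enzyme of astrocytes, 11.6 ± 1.38 and 47.9 ± 11.2 (2.04 ± 0.24). On the lower side were Pcp4, a calmodulin regulator (389 ± 102 and 173 ± 42.6, −1.17 ± 0.24), Pde1b, a phosphodiesterase of dopamine-receptive neurons (174 and 78.8, −1.14 ± 0.27), and Clspn, a replication checkpoint gene (6.17 ± 2.48 and 1.04 ± 0.709, −2.60 ± 0.52). Selenow was at 297 ± 99.4 and 123 ± 36.8 (−1.27 ± 0.30). All 7 separated the groups in 5 of 5 mutants except Pde1b, in 4 of 5, and chance gives full separation, in either direction, in 3.57% of genes. Most were picked by a small p, so their separation adds no support. None passed the unpaired edgeR test, where adjusted p was 0.1005 for Etnppl, 0.285 for Gfap and C4b, 0.320 for Pcp4 and Clspn, 0.514 for Pde1b and 0.516 for Selenow. The replicate block in effect compares mutants 1 to 3 with the 3 controls, on few residual degrees of freedom. The labels do not give this pairing, and it is used here because these same counts correlated by number. With it the adjusted p was 0.00142 for Etnppl, 0.00366 for Gfap, 0.00736 for C4b, 0.0338 for Pcp4 and Selenow, 0.0139 for Pde1b and 0.0926 for Clspn. Over the alternatives adjusted p ranged from 5.91e-10 to 0.988 for Etnppl, 5.94e-09 to 0.988 for Gfap and 2.17e-07 to 0.988 for C4b. Cst7, chosen after its values were seen, was at 0.303 mean CPM in controls and 35.4 in mutants.

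Over all genes in the P75 cortex, edgeR called 0 of 13291, 726 had an unadjusted p under 0.05, and limma-voom called 0. DESeq2 called 53 (41 higher, 12 lower), and the blocked edgeR test 48 (22 higher, 26 lower). Leaving out mutant 1 gave 2 calls, with adjusted p of 0.0124 for C4b and 0.0128 for Gfap, and leaving out mutant 5 gave 1, Etnppl (0.0395). Control 2 and mutant 2 shared a pattern described with the library differences. The unpaired test with a term for the libraries numbered 2 called 88 genes (47 higher, 41 lower).

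Microglia and macrophage markers were 23 higher and 0 lower of 23 in the P75 cortex, with a median of 1.13 and 5 of 5 mutants above all controls. They included the lysosomal protease Ctss (110 ± 21.9 and 400 ± 151 CPM, 1.86 ± 0.34) and the complement genes C1qb (1.89 ± 0.37; adjusted p with the block 0.0376) and C1qc (1.81 ± 0.37). Camera called the list with adjusted p = 3.52e-17 (2.26e-10 with the block), and adjusted p = 0.175 with an estimated correlation. Of its genes 12 passed adjusted over the list alone, against 0 over all genes. Interferon-stimulated genes were 27 higher and 0 lower of 27, with a median of 1.04 and 3 of 5 mutants above all controls, such as H2-D1 (1.07 ± 0.29), Ifit3 (1.88 ± 0.53) and Ifi44 (1.98 ± 0.61). Their adjusted p was 5.80e-14 (2.81e-06 with the block, median 0.57), with adjusted p = 0.378 with an estimated correlation. By edgeR 14 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone or over all genes. Astrocyte markers had a median of 0.31 with 15 of 19 higher and 4 of 5 mutants above all controls, such as Clu (0.71 ± 0.26) and Apoe (0.62 ± 0.25). Their adjusted p was 5.68e-04 (1.82e-05 with the block), with adjusted p = 0.495 with an estimated correlation. Gfap alone passed adjusted over the list alone, and the call was lost without mutant 2 (median 0.21).

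**Figure D2:**
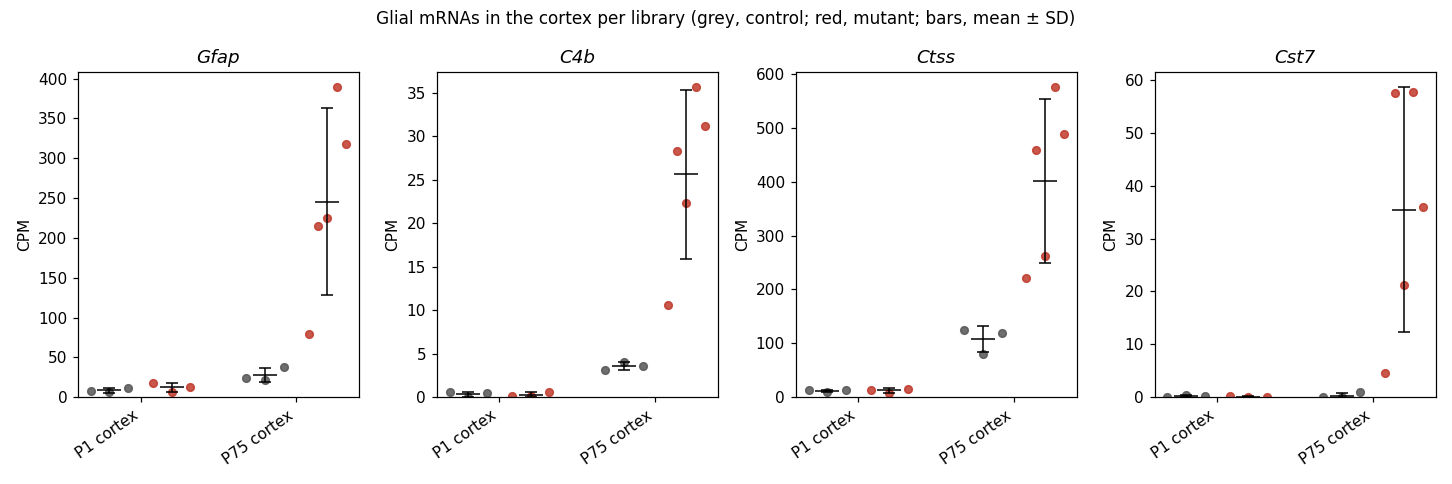
CPM of the library total of Gfap, C4b, Ctss and Cst7 for each cortex library at P1 and P75 (grey, control; red, mutant; bars, mean ± SD). All 5 P75 mutants lie above all 3 P75 controls for each gene, with 79.4 to 389.2 CPM of Gfap against 21.4 to 37.8.

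Markers of striatal neurons, the brain region under the cortex, were 0 higher and 17 lower of 17 in the P75 cortex, with a median of −1.94 and 4 of 5 mutants below all controls. Pde10a was at 117 ± 10.5 and 38.65 ± 23.99 CPM (−1.61 ± 0.43; adjusted p with the block 0.0405), Rarb had −1.70 ± 0.57 (0.0497) and Syndig1l −2.12 ± 0.75 (0.0562). Camera called the list with adjusted p = 1.22e-14 (2.53e-16 with the block), and adjusted p = 0.378 with an estimated correlation. By edgeR 7 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone, and with the block 3 passed over all genes. Choroid plexus markers were 6 of 6 higher, with a median of 1.98 and 5 of 5 mutants above all controls (9.19e-07, 1.52e-05 with the block, and adjusted p = 0.175 with an estimated correlation), 5 of them adjusted over the list alone. They included the thyroxine carrier Ttr (36.5 ± 32.6 and 609 ± 724 CPM, adjusted p with the block 0.0396), Otx2 (3.36 ± 0.79) and Prlr (3.02 ± 0.84). Meningeal markers were 11 of 12 higher, with a median of 0.45 and 4 of 5 mutants above all controls (1.41e-04, 0.00352 with the block, and adjusted p = 0.193 with an estimated correlation). Ptgds (663 ± 50.2 and 1268 ± 236 CPM) and Slc6a20a (0.72 ± 0.18) passed adjusted over the list alone. Transcripts of heart muscle were also counted: Tnnt2 was at 6.59 ± 0.123 and 25.6 ± 27.8 CPM, Myl3 at 6.49 ± 2.04 and 33.2 ± 40.6, and Actn2 at 9.70 ± 1.07 and 4.45 ± 2.90. The cardiomyocyte list had a median of 0.80 with 15 of 22 higher and 3 of 5 mutants above all controls (0.0288, 0.923 with the block, and adjusted p = 0.726 with an estimated correlation). This call was lost without mutant 5 (median 0.15), control 1 (0.73) or control 3 (0.94).

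Camera called further lists in the P75 cortex, none of them with an estimated correlation. Cholesterol synthesis genes were 0 higher and 24 lower of 24, with a median of −0.46 and 5 of 5 mutants below all controls, among them Cyp51 (−0.61 ± 0.18) and Sqle (−0.55 ± 0.18). Their adjusted p was 1.35e-12 (4.92e-09 with the block), with adjusted p = 0.175 with an estimated correlation. By edgeR 12 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone. Glucocorticoid-responsive genes had a median of 0.70 with 17 of 19 higher and 4 of 5 mutants above all controls (1.82e-07, 6.08e-11 with the block, and adjusted p = 0.175 with an estimated correlation). Mt1, a metal-binding protein (0.99 ± 0.17; adjusted p with the block 0.0394), the transcription factor Klf15 (1.03 ± 0.19; 0.0808) and the cell-cycle inhibitor Cdkn1a (1.16 ± 0.32; 0.0338) led the list, and 3 genes passed adjusted over the list alone. Ribosomal protein genes had a median of 0.19 with 56 of 69 higher (6.02e-04, 0.00156 with the block, and adjusted p = 0.175 with an estimated correlation), such as Rps9 (0.45 ± 0.17) and Rpl23 (0.52 ± 0.21). Fatty acid oxidation genes (median 0.23, 22 of 27 higher; Eci1 0.76 ± 0.34 and Decr1 0.56 ± 0.27) passed at 0.0316 but not with the block (0.155), and adjusted p = 0.497 with an estimated correlation. Myelin genes (median −0.16, 18 of 22 lower; Mag −0.58 ± 0.25 and Gjb1 −0.77 ± 0.30) passed at 0.0132, with adjusted p = 0.726 with an estimated correlation. The fatty acid call was lost without control 1 (0.15), control 2 (0.13), mutant 2 (0.20) or mutant 5 (0.16), and the myelin call without control 3 (−0.05), mutant 2 (−0.08) or mutant 3 (−0.10).

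Of 21 selenoproteins tested in the P75 cortex, 10 were higher and 11 lower by edgeR, and 0 passed over all genes. Selenop, the plasma selenium carrier (0.70 ± 0.16), was higher, and Selenow and Gpx1 (−0.93 ± 0.27) were lower, when adjusted over the list alone. With the block Selenow and Gpx1 (adjusted p = 0.0342) passed over all genes. Selenoh had −0.53 ± 0.18, below all controls in 5 of 5. The count adjusted over the list alone was 0 without control 1, 1 without control 3, and 5 without control 2 or without mutant 2. The selenium-sensitive list had a median of −0.51 with 5 of 5 mutants below all controls (7.73e-04, 0.00266 with the block, and adjusted p = 0.175 with an estimated correlation), and 3 of its genes passed adjusted over the list alone. The median of all selenoproteins was −0.07 by the edgeR fold changes and 0.03 by log2 CPM, with a mean of 0.02, while the camera test pointed down (adjusted p = 0.768).

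The P75 heart comparison asked the same of the adult heart, and 2 genes passed. Selenoh (ENSMUSG00000076437; chromosome 2, 84669215 to 84670770) fell from 19.1 ± 5.31 CPM in 3 controls to 3.43 ± 0.605 in 5 mutants (−2.47 ± 0.28, adjusted p = 0.0208). Gsta2 (ENSMUSG00000057933; chromosome 9, 78331018 to 78355788), a glutathione transferase that clears lipid peroxidation products, rose from 0.321 ± 0.142 to 15.8 ± 7.77 CPM (5.59 ± 0.64, adjusted p = 0.0208). Its split from Gsta1, a near-identical paralog, is uncertain. Each gene separated the groups in 5 of 5 mutants. Next came Gsta4, which conjugates the lipid aldehyde 4-hydroxynonenal (38.6 ± 14.4 and 177 ± 31.4 CPM, 2.19 ± 0.33), Gclm, a subunit of the enzyme that starts glutathione synthesis (15.96 ± 2.37 and 92.7 ± 39.8, 2.54 ± 0.39), and Nqo1, a quinone reductase (24.2 ± 5.23 and 144 ± 55.9, 2.57 ± 0.39). They were higher in 5 of 5 mutants and did not pass (adjusted p = 0.0612 each). Selenow was at 58.4 ± 23.8 and 16.5 ± 6.27 CPM (−1.81 ± 0.36, adjusted p = 0.171), lower in 5 of 5. Of 12264 genes, 960 had an unadjusted p under 0.05, DESeq2 called 96 (40 higher, 56 lower) and limma-voom 17. Over the alternatives adjusted p ranged from 1.27e-09 to 0.638 for Selenoh and from 7.35e-09 to 0.368 for Gsta2. Both calls were lost in 7 of the 8 fits that left out 1 library, with adjusted p of 0.170 without control 1 for each, 0.0670 and 0.213 without control 2, and 0.0695 and 0.102 without control 3, for Selenoh and Gsta2 in turn. They were 0.0698 for each without mutant 1, 0.0992 and 0.0781 without mutant 3, 0.129 and 0.113 without mutant 4, and 0.0550 for each without mutant 5. Without mutant 2, 10 genes passed, these 2 among them.

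NRF2 targets were 25 higher and 4 lower of 29 in the P75 heart, with a median of 0.96, a mean of 1.24 and 5 of 5 mutants above all controls. Camera called the list with adjusted p = 3.90e-19, which held at adjusted p = 0.0316 with an estimated correlation, and it was the 1 list of the 4 comparisons that did. In this list 15 genes were higher and 0 lower adjusted over the list alone, against 1 over all genes. The call at the preset correlation held without any 1 of the 8 libraries, while that with an estimated correlation was lost in 6 of the 8 fits. It gave an adjusted p of 0.0826 without control 2, 0.254 without control 3, 0.0586 without mutant 1, 0.228 without mutant 2, 0.0552 without mutant 3 and 0.0626 without mutant 4, against 0.0420 without control 1 and 0.0244 without mutant 5. Other antioxidant enzymes were 21 of 26 higher, with a median of 0.31 and 5 of 5 mutants above all controls (adjusted p = 0.00253, and adjusted p = 0.264 with an estimated correlation). Catalase, Cat, was at 124 ± 43.9 and 370 ± 74.7 CPM (1.58 ± 0.33) and alone passed adjusted over the list alone, and Prdx1 had 1.01 ± 0.36. Genes of ferroptosis, cell death by lipid peroxidation, were 16 of 24 higher, with a median of 0.24 and 5 of 5 mutants above all controls (0.0469, and adjusted p = 0.320 with an estimated correlation). The ferritin chain Fth1 (1223 ± 521 and 4084 ± 1217 CPM, 1.74 ± 0.41) was higher and the lipoxygenase Alox5 (−1.08 ± 0.30) lower, adjusted over the list alone. The antioxidant call was lost without mutant 2 (median 0.23), and the ferroptosis call without control 3 (0.37), mutant 2 (0.31), mutant 3 (0.27) or mutant 4 (0.27).

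**Figure D3:**
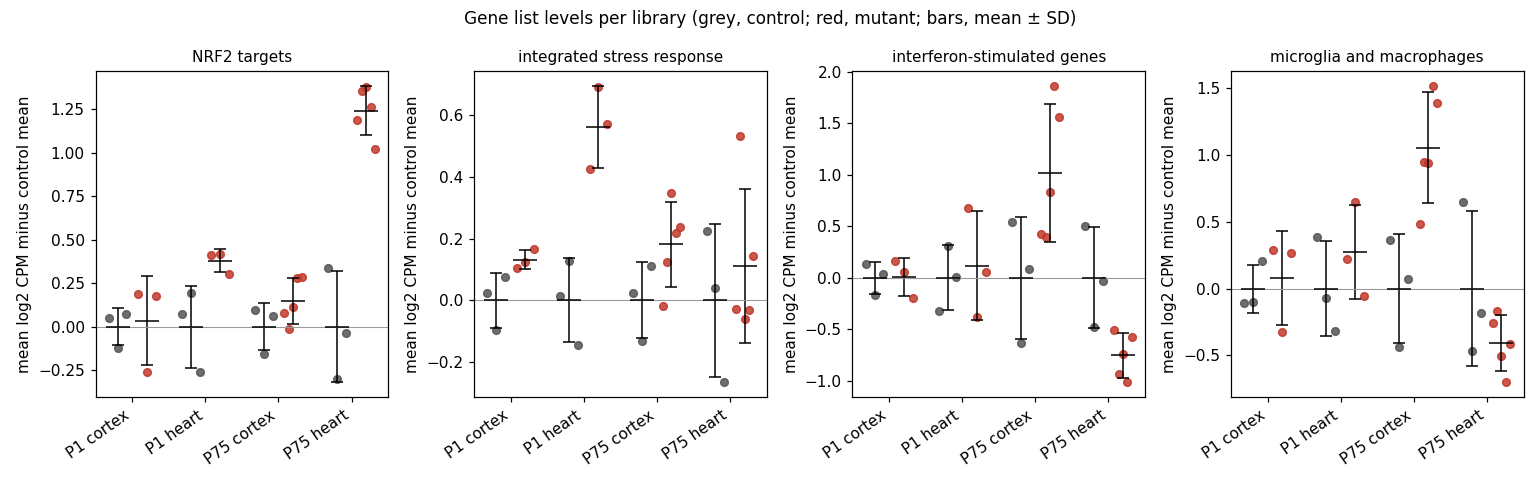
Mean log2 CPM of the genes of 4 lists in each library, minus the control mean of its comparison (grey, control; red, mutant; bars, mean ± SD). NRF2 targets lie above all controls in 5 of 5 P75 heart mutants, stress response genes in 3 of 3 P1 heart mutants and microglia markers in 5 of 5 P75 cortex mutants, and interferon-stimulated genes lie above all controls in 3 of 5 P75 cortex mutants and below them in 5 of 5 P75 heart mutants.

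Interferon-stimulated genes were 1 higher and 27 lower of 28 in the P75 heart, with a median of −0.56 and 5 of 5 mutants below all controls (adjusted p = 2.30e-09, and adjusted p = 0.264 with an estimated correlation). Of these 7 were lower adjusted over the list alone, against 0 over all genes. Isg15 averaged 28.8 ± 35.7 and 3.68 ± 1.15 CPM and Bst2 159.5 ± 238 and 12.1 ± 5.00, with control SD above the control means, while Rsad2 (76.1 ± 18.9 and 27.6 ± 12.4) and Ifi44 (9.01 ± 2.65 and 2.74 ± 0.972) had closer controls. Cell-cycle genes were 16 of 20 lower, with a median of −0.48 and 5 of 5 mutants below all controls (4.64e-04, and adjusted p = 0.264 with an estimated correlation). Of these Top2a (−2.84 ± 0.54) and Birc5 (−2.15 ± 0.61) passed adjusted over the list alone, against 0 over all genes. Both calls held without any 1 library. Lymphoid markers (1.72 ± 0.114 log2 CPM in controls and 1.26 ± 0.838 in mutants) and skeletal muscle markers (4.70 ± 0.209 and 4.21 ± 0.342) were below all controls in 4 of 5 of the same mutants and were not called (adjusted p = 0.319 and 0.129). Macrophage markers were 17 of 22 lower, with a median of −0.27 and 5 of 5 mutants below the control mean (0.0329, and adjusted p = 0.759 with an estimated correlation). Aif1 (−2.22 ± 0.50) and Cx3cr1 (−1.83 ± 0.46) passed adjusted over the list alone, and the call was lost without control 1 (−0.03), control 3 (−0.18) or mutant 4 (−0.17). The fetal and stress genes of heart muscle had a median of 0.61 with 17 of 23 higher and 4 of 5 mutants above the control mean (0.00633, and adjusted p = 0.320 with an estimated correlation). They included Uchl1 (1.00 ± 0.26), Flnc (0.84 ± 0.24) and the slow myosin Myh7 (19.6 ± 6.81 and 44.3 ± 17.8 CPM). Markers of the atria were not called (adjusted p = 0.0931, and adjusted p = 0.819 with an estimated correlation), at a mean of 4.08 ± 1.66 log2 CPM in controls and 5.51 ± 2.26 in mutants, with 3 of 5 mutants above all controls. Glucocorticoid-responsive genes had a median of 0.50 with 17 of 20 higher and 4 of 5 mutants above the control mean (0.00311, and adjusted p = 0.720 with an estimated correlation), with Klf15 (1.38 ± 0.35) past the threshold adjusted over the list alone. The muscle stress call was lost without control 3 (0.71) or mutant 2 (0.46), and the glucocorticoid call without control 3 (0.25) or mutant 2 (0.29). In all, 9 of 46 lists were called, and 18 without control 1 and 5 without control 3.

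Of 20 selenoproteins tested in the P75 heart, Selenoh passed over all genes. Selenoh and Selenow were lower, and Txnrd1 (1.28 ± 0.27), which is also an NRF2 target, and Selenoo (1.07 ± 0.31) were higher, adjusted over the list alone. This count of 4 was 7 without mutant 2. Gpx1 was at 197.1 ± 79.2 and 99.0 ± 67.8 CPM, below all controls in 4 of 5 mutants. The selenium-sensitive list had a median of −1.10 (−0.9952 by the edgeR fold changes) with 5 of 5 mutants below all controls (adjusted p = 0.00284, and adjusted p = 0.264 with an estimated correlation). The median of all selenoproteins was 0.04 while their mean was −0.16 and the camera test pointed down (adjusted p = 0.656).

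The P75 libraries fell into sets that the groups do not explain. Ccdc36, a meiotic gene, was at 968.4 and 781.5 CPM in cortex control 2 and mutant 2, and at 245.1, 407.1 and 504.6 CPM in heart control 1, control 2 and mutant 2. It was at most 10.0 CPM in the other P75 libraries. Albumin mRNA was at most 0.211 CPM in the 4 P75 libraries numbered 2 and 24.1 to 205.2 CPM in the others. Heart control 1 had 40.7% of counts on mitochondrial genes against 17.8% to 29.1% in the other P75 hearts. With a term for the Ccdc36-high hearts, edgeR called 25 genes (15 higher, 10 lower), the NRF2 list had a median of 1.03 (adjusted p = 0.139 with an estimated correlation, no longer called by that test), the interferon list −0.73 and the macrophage list −0.16, no longer called. Within the 3 Ccdc36-high hearts the NRF2 median was 1.45 (1 mutant against 2 controls), and within the 5 others 0.89 (4 mutants against 1 control).

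Whether the effect of the mutation differs between tissues was tested as an interaction. Over all genes, edgeR called 0 of 15157 at P1 (371 at an unadjusted p under 0.05, DESeq2 0, limma-voom 0; 2 calls without heart control 3). At P75 it called 0 of 14814 (945 at an unadjusted p under 0.05, DESeq2 58, limma-voom 2; 1 call without heart mutant 4). By camera, added after the comparisons were seen, 17 of 50 lists differed at P1, and 0 with an estimated correlation. The stress response was higher in heart than in cortex by 0.39 (3.60e-04, and adjusted p = 0.127 with an estimated correlation) and cholesterol synthesis lower by a median of −0.55 (1.08e-05, and adjusted p = 0.478 with an estimated correlation), with 1 gene of each list past the threshold adjusted over the list alone and 0 over all genes. At P75, 7 of 50 lists differed. NRF2 targets (0.91, 24 of 30 higher in heart, adjusted p = 0.0114 with an estimated correlation) and cell-cycle genes (−0.88, 25 of 28 lower, adjusted p = 0.0499 with an estimated correlation) held with an estimated correlation. With a term for the Ccdc36-high libraries these were adjusted p = 0.0181 and 0.2795 with an estimated correlation, so that of cell-cycle genes was lost. Interferon-stimulated genes (−1.61, 29 of 29 lower) and microglia markers (−1.55, 22 of 23 lower) differed by the preset test (7.99e-22 and 2.25e-14), with adjusted p = 0.119 with an estimated correlation for each. The counts adjusted over the list alone were 7 NRF2 targets, 2 cell-cycle, 17 interferon-stimulated and 12 microglia genes, against 0 over all genes.

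Between ages the effects were compared in the same way, with age and the Gpx4 allele differing together. Sex differs as well, since Xist was above Ddx3y in 3 of 3 mutants of each P1 tissue and in 1 of 5 of each P75 tissue, and the P1 heart groups differ in kit. In cortex edgeR called 0 of 14806 genes (521 at an unadjusted p under 0.05, DESeq2 1, limma-voom 0). With the replicate block, where P75 cortex numbers may pair and P1 cortex numbers do not, it called 5, of which 3 were Y-linked. The others, Foxp2 (−1.64 ± 0.19) and Gabra2 (−1.84 ± 0.27), had a lower effect at P75. In heart edgeR called 0 of 13714 (529 at an unadjusted p under 0.05, DESeq2 6, limma-voom 0; 1 call without P1 heart control 2). In cortex 11 of 48 lists differed, among them microglia markers (1.14, 23 of 23 higher at P75, 2.07e-12) and striatal markers (−2.31, 17 of 17 lower, 1.50e-12), with adjusted p = 0.438 with an estimated correlation for both. In heart 10 of 50 differed. NRF2 targets were higher at P75 by 0.86 (22 of 29 higher, adjusted p = 0.0406 with an estimated correlation, and 0.1037 and lost with a term for the Ccdc36-high libraries) and stress response genes lower by a median of −0.35 (27 of 36 lower, 0.00927, adjusted p = 0.514 with an estimated correlation, and lost with that term), which rests on the P1 heart rise that Xist level lowers to 0.12. Adjusted over the list alone 6 NRF2 targets and 5 cortex microglia genes passed, against 0 over all genes. Between the tissues of an age, 0 genes were called in both by edgeR. DESeq2 called Selenow lower in both P1 tissues (0.00121 genes by chance among 11600) and in both P75 tissues (0.0277 by chance among 11112), and Ptgds and Klf15 higher in both P75 tissues (0.0835 by chance).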

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

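The tests of the Ccdc36-high libraries, liver RNA, the number-2 libraries, striatal tissue, the extraction kit and sex were chosen only after the result was seen, and those of other splits, lung and border macrophages before. A library counted as far from its group where its gap to the next library, over the range of the group, exceeded Dixon's 95% value. The rule was applied to 50 sets of 5 values, which are many measures on the same 2 groups of 5 libraries and so not independent, and chance picks about 1 in 20 sets. In the P75 cortex mutants, mutant 2 had the highest Gpx1 (153.1 CPM) and Ccdc36 (781.5 CPM). In the P75 heart mutants, mutant 2 had the highest Gpx1 (205.2 CPM), Ccdc36 (504.6 CPM) and Scgb3a2 (161.2 CPM). A difference between groups was noted where the interaction test of a list held with an estimated correlation. At P75 this was so for NRF2 targets, higher in heart than in cortex (median 0.9076 over 30 genes, adjusted p = 0.0114), and for cell-cycle genes, lower in heart (−0.8848 over 28 genes, adjusted p = 0.0499). With a term for the Ccdc36-high libraries the adjusted p of these were 0.0181 and 0.2795, the latter lost. Between ages it was so for NRF2 targets in heart, higher at P75 (0.8581 over 29 genes, adjusted p = 0.0406, and 0.1037 with that term, lost), where age, the Gpx4 allele, sex and the P1 heart kit differ together.

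Other splits of the P75 libraries show a structure of the samples that the groups do not explain. In the P75 heart the split of control 1, control 2 and mutant 2 against the other 5 gave 2298 calls, against 2 for the real groups. In all, 2 of 56 splits gave as many as the real one. With 2298 calls in the other of these, the splits cannot exclude chance for a count of 2. The count is unstable, at 10 without mutant 2, 0 without any other 1 library and 0 with the replicate block, and the contrast with the most calls in these hearts is another one. In the P75 cortex the split of control 1, control 2 and mutant 2 against the other 5 gave 1291 calls against 0. With a real count of 0, all 56 of 56 splits give as many by construction, so the splits say nothing on that count, nor on the 48 calls of the blocked fit, since they used the unpaired one. Among the 8 splits that part the 3 same-number pairs of the P75 cortex, the real one included, the others gave at most 0 calls, 12 lists, a microglia median of 0.921 and a striatal median of 1.69 in size. For the number of lists, 4 of 56 splits of the P75 cortex (13 in the real groups, highest other 15) and 28 of 56 of the P75 heart (9, highest other 16) gave as many, so chance cannot be excluded for either count.

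At P1 each comparison has 10 splits, too few for a share under 0.05. In the P1 cortex the real groups gave 0 calls and the highest other split 306, control 1, control 2 and mutant 2 against the rest, which points to a structure of the samples. In the P1 heart they gave 0 and 6. With a real count of 0, all 10 of 10 splits of each give as many by construction. For the lists the P1 cortex gave 6 and 20 (10 of 10 splits as many) and the P1 heart 15 and 20 (3 of 10). For the interactions the real count was 0 as well, so that 100 of 100 splits give as many by construction, and the highest other gave 41 (P1 tissues), 2 (P75 tissues), 4 (cortex ages) and 2 (heart ages).

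NRF2 targets were higher in the P75 heart mutants (median 0.963), and 1 of 56 splits, the real one, gave a median as large. That share is under 0.05, but the highest other split came close in size (0.940). That other split had the sign reversed. It set mutants 1 to 3 against the controls with mutants 4 and 5, so it held part of the same contrast. The share also does not allow for the choice of this list among 46, so chance is made less likely and not excluded. With a term for the Ccdc36-high libraries the median was 1.026. The camera call stood at the preset correlation and was lost with an estimated one (adjusted p = 0.139). This fit rests on 1 mutant among the Ccdc36-high hearts and 1 control among the others, so it cannot exclude these libraries as a cause. Lung tissue in mutants 2, 4 and 5 is argued against by a median of 0.975 in mutants 1 and 3 alone (camera adjusted p = 1.36e-13). Liver RNA, where many of these enzymes are high, stays open, since 8 liver genes had a median of −0.9252 but a standard error over libraries of 1.741 for their mean level. The biological explanation, the mutant genotype, remains possible. Open is whether the Gpx4 allele, the Sepsecs allele or both go with it, since no P75 group is labelled as carrying 1 of them alone.

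Microglia and macrophage markers were higher in the P75 cortex mutants (median 1.13), and 2 of 56 splits gave a median as large (highest other 1.20). That share is under 0.05, but it does not allow for the choice of this list among 46. The 8 splits that part the 3 same-number pairs are too few for a share under 0.05 (highest other 0.921). Chance therefore cannot be excluded for this rise. The number-2 libraries do not account for all of the rise, since the median without them was 0.8461 against 1.13 with them. Part of its size may go with them. Less striatal tissue is argued against by a median of 0.0655 for 21 excitatory-neuron markers (SE over libraries 0.2516 for their mean level). Macrophages of the meninges or choroid plexus could account for part of it: 7 of 7 parenchymal microglia genes were higher, with a median of 0.6593 (SE over libraries 0.2759 for their mean level), and 4 of 4 border macrophage genes, with 0.801. The parenchymal median reached the share of the list median set before the result was seen. It did not with 2 SE taken off, an allowance that the rule did not name, so a part from border macrophages stays open. The striatal markers beside it gave a median as large in size in 6 of 56 splits (1.94 in the real groups, highest other 2.66), so chance cannot be excluded for them, and the piece of cortex taken may differ between mice. Whether microglia are more numerous or more active in the mutant cortex, the biological explanation, stays open.

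Stress response genes were higher in the P1 heart mutants (median 0.388, highest other split 0.242), and 1 of 10 splits gave as much, with too few splits for a share under 0.05. The list level was 4.163, 4.276 and 4.004 log2 CPM in controls 1 to 3 and 4.573, 4.838 and 4.720 in mutants 1 to 3. The RNeasy control lay at −43.85% of the way from the TRIzol controls to the mutants, away from them, and the Xist-expressing control at 30.64% of the way from the other controls. With 1 control of each kind neither the kit nor sex can be excluded, and the covariate for Xist lowered the median to 0.12. Airway and cartilage genes were high in the TRIzol controls, so neighbouring tissue in them cannot be told apart from the kit. The mutant genotype, the biological explanation, remains possible.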

How the results depend on the processing

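The settings with a term for or without certain P75 libraries, and the list tests with Xist, were chosen only after the result was seen. Over all settings, 253 recomputed counts stayed within 1.5 times the main count, and 89 did not. Of the list results 395 kept direction and call, 164 kept the direction and lost the call, and 7 changed the direction of the test. Of the named-gene results 2320 kept both, 128 gained a call, 17 lost 1, and 15 changed sign. The cause was not tested for any changed value except where fewer samples or genes show it. Depth limits genes near 1 CPM, where the smallest library holds about 3 counts.

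With DESeq2 the calls were 3 in the P1 cortex, 10 in the P1 heart, 53 in the P75 cortex, 96 in the P75 heart, 58 for the P75 tissues, 1 for the cortex ages and 6 for the heart ages. DESeq2 also gave 5 selenoproteins adjusted over the list alone in the P75 cortex, 1 call shared between the P1 tissues and 3 between the P75 tissues. With no filter on low counts edgeR called 52, 118, 11 and 72 genes in the P1 cortex, P1 heart, P75 cortex and P75 heart, 42 and 14 for the P1 and P75 tissues, 10 and 158 for the cortex and heart ages, and 4 selenoproteins adjusted over the list alone in the P1 heart. Upper-quartile normalization gave 8 calls in the P75 heart and an adjusted p under 0.10 gave 18. Limma-voom gave 17 there, 2 for the P75 tissues, 6 selenoproteins adjusted over the list alone in the P75 cortex and a Gpx4 log2 fold change of 0.63 in the P75 heart, with its sign reversed. All 4 groups of a tissue in 1 fit gave 1, 1, 4 and 33 calls in the P1 cortex, P1 heart, P75 cortex and P75 heart, and 3 selenoproteins adjusted over the list alone in the P1 cortex. RNeasy libraries alone gave 4 calls in the P1 heart, where fewer samples were tested.

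The replicate block, set beside the main test there because these same counts correlated by number, gave 48 calls in the P75 cortex. For the cortex ages, where only the P75 numbers may pair, the block gave 5 calls. Where the numbers do not pair, the block gave 2 calls in the P1 heart, 0 in the P75 heart, 3 for the heart ages and a Gpx4 value of 0.0479 in the P75 heart, with its sign reversed. There the block also ended the calls of Selenoh (adjusted p = 0.638), Gsta2 (0.368) and macrophage markers (median −0.09). The NRF2 list of the P75 heart lost its call with an estimated correlation (adjusted p = 0.412) and by fry (0.150). At the preset correlation the block added calls of fibroblast (−0.30), striatal (0.41) and hippocampal markers (0.36) in the P1 cortex, of atrial (1.32) and neutrophil markers (1.53) in the P75 heart, and of stress response genes (0.11), neutrophil (0.55) and hippocampal markers (0.45) in the P75 cortex. Fry with the block called 2 lists in the P1 heart, selenoproteins and neutrophil markers. With Xist level as a covariate the P1 cortex had 9 calls and 14 lists, and these values changed sign: cell cycle in the P1 cortex 0.11, and in the P1 heart Gpx4 0.14, Sepsecs −0.16, erythroid genes −0.23 and glucocorticoid-responsive genes −0.29. Gpx4 in the P75 heart became 0.13. The camera test with an estimated correlation called 0, 0, 0 and 1 lists in the P1 cortex, P1 heart, P75 cortex and P75 heart, and fry called 0, 0, 0 and 1. For that 1 list, NRF2 targets, the adjusted p with an estimated correlation was also above 0.05 with Xist level (0.0845), with a term for the number-2 libraries (0.152) or without them (0.561), and without them and control 1 (0.608), where fry lost it too (0.236). Leaving out each library, the fry call stood in 8 of 8 fits.

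A term for the P75 libraries numbered 2 gave 88 calls in the P75 cortex, 4 in the P75 heart, 27 for the P75 tissues and 7 selenoproteins adjusted over the list alone in the P75 cortex. Without those libraries there were 3 and 4 calls in the P75 cortex and heart, 7 selenoproteins adjusted over the list alone in the P75 cortex and a Sepsecs value of 0.006966 in the P75 heart. A term for the libraries with Ccdc36 above 100 CPM gave 25 calls in the P75 heart and 37 for the P75 tissues. Without the number-2 libraries and control 1 the P75 heart had 13 calls, 15 lists and a Gpx4 value of 0.87.

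Leaving out each library in turn, calls ranged from 0 to 5 in the P1 cortex (5 without control 1, 1 without mutant 3), 0 to 14 in the P1 heart (14 without control 3, 3 without control 2, 1 without mutant 2), 0 to 2 in the P75 cortex (2 without mutant 1, 1 without mutant 5) and 0 to 10 in the P75 heart (10 without mutant 2, 0 without any other). They ranged from 0 to 2 for the P1 tissues (2 without heart control 3), 0 to 1 for the P75 tissues (1 without heart mutant 4) and 0 to 1 for the heart ages (1 without P1 heart control 2). Selenoproteins adjusted over the list alone ranged from 3 to 6 in the P1 cortex (3 without control 1, mutant 1 or mutant 3, 4 without control 2), 0 to 5 in the P75 cortex (0 without control 1, 1 without control 3, 5 without control 2 or mutant 2) and 3 to 7 in the P75 heart (7 without mutant 2). Lists called ranged from 5 to 10 in the P1 cortex (10 without control 3, mutant 2 or mutant 3), 9 to 17 in the P1 heart (9 without control 1) and 5 to 18 in the P75 heart (18 without control 1, 5 without control 3). Directions changed for these values. The median of cell-cycle genes ranged from −0.33 to −0.0251 in the P1 cortex, where without mutant 1 the median stayed negative while the test pointed up. In the P1 heart it ranged from −0.54 to 0.18 (0.15 without control 3, 0.18 without mutant 2), and that of glucocorticoid-responsive genes from −0.0679 to 1.11 (−0.0679 without control 1). Sepsecs ranged from −0.00244 (without control 1) to 0.27 in the P1 heart and from −0.40 to 0.0025 in the P75 heart (0.0025 without control 3, 0.00046 without mutant 2). Gpx4 ranged from −0.21 to 0.0808 in the P1 heart (0.0257 without control 3, 0.0808 without mutant 1) and from −0.35 to 0.71 in the P75 heart (0.71 without control 1, 0.06 without mutant 2, 0.03 without mutant 5).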

Other observations

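The combined test over the 4 comparisons, the calls with a Ccdc36 term and the tests of both hypotheses below were chosen only after the result was seen, as were the genes named here. Combining signed z values of the 4 comparisons, 16 of 10480 genes passed, though libraries of the 2 tissues of an age may share animals, which would make these p values too small. Selenow and Selenoh (adjusted p = 2.83e-09 each), Gpx1 (0.00192) and Apln, the apelin peptide of vessels (3.26e-06), were lower. Apln averaged 5.79 and 2.19 CPM of the library total in P1 cortex controls and mutants, 20.8 and 5.48 in the P1 heart, 35.9 and 20.9 in the P75 cortex, and 18.5 and 3.39 in the P75 heart. Higher were the glutathione transferases Gstm1 (0.0011) and Gsta4 (0.0139), the quinone reductase Nqo1 (0.0139), Klf15 and Ptgds (0.00468 each) and Mt1 (0.0159). With a term for the Ccdc36-high hearts, 15 genes were higher and 10 lower in the P75 heart, among them Gclm (2.78), Nqo1 (2.43), Gstm1 (2.69), Mt2, a metallothionein (2.87), and Lcn2, which binds iron carriers (2.53), and lower Apln (−3.44), Selenoh (−2.37) and Nrep (−2.31).

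The first hypothesis was that the selenoprotein mRNAs known to follow selenium supply fall while the other selenoprotein mRNAs do not. Of the 5 selenium-sensitive mRNAs 3 (Selenow, Selenoh and Gpx1) were lower in all 4 comparisons, and 0 of 15 others (one-sided Fisher's exact p = 0.00877), while 999 of 10480 genes, 9.53%, were lower in all 4. The list was fixed without sight of the values, the test after the 3 genes had been seen, so the test restates what prompted it and gives no independent support. Other selenoproteins were lower in single comparisons, such as Selenom (−0.73 ± 0.29 in the P1 heart and −1.45 ± 0.48 in the P75 heart) and Selenok (−0.53 ± 0.22 in the P1 heart), without passing over all genes. The hypothesis stays open. Gpx3 and Msrb1, the other 2 of the list, were not lower in all 4.

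The second hypothesis was that Gabra2 differs in the P1 cortex through a strain variant near Sepsecs rather than through the mutation. Gabra2 lies on the chromosome of Sepsecs (chromosome 5, 70957597 to 71095849). In the P1 cortex controls had 13.2 to 26.6 CPM and mutants 55.5 to 95.4, while in the P75 cortex all libraries lay between 100.1 and 137 CPM, with a log2 fold change of 0.03626 ± 0.14. The test cannot tell: a variant carried with the mutation should show at P75 as well, unless the P75 controls carry it too, and their genotype at this gene is not given in the sources used here.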
